A study of Mus musculus with 27 samples.

How the data were processed

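Polyadenylated RNA of mouse embryonic stem cells with a conditional Dicer allele was sequenced with reads of 100 bases from 27 libraries in 9 groups of 3, namely whole cells on 5 days from day 0 to day 12 and nuclear and cytoplasmic fractions on the first and last of these. Per the file headers, the authors deposited an FPKM value (fragments scaled for transcript length and library size) for each of 38123 genes in each library. The submitters' processing notes name TopHat2 2.0.9, Cufflinks 1.3.0 and the genome build mm9, with no role or order. The annotation, strand setting and treatment of reads with several matches are not given in the sources used here. FPKM is relative within a library, so a value in a fraction says nothing about the amount of RNA in that fraction. The 3 files labelled day 12 of whole cells were written in another format, with more decimals and unsorted genes, and were joined to the others by gene identifier. Of the genes, 36253 had a symbol. FPKM sums were 275545 to 459892 per library, correlations within groups 0.908 to 0.993, and no 2 libraries held identical values. The replicates are named as biological replicates per the labels, with no word on separate cultures or days, so p-values measure the spread between these libraries.

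Groups were taken from the labels. FPKM values were tested on the scale log2(FPKM + 0.5) with limma 3.58.1 in R 4.3.3, with eBayes and a trend, and Benjamini-Hochberg adjustment at 0.05. A fold on this scale understates the change of low genes. Genes with a mean of at least 0.5 FPKM in 1 group of a fit were kept, 15991 in whole cells and 17124 in the fractions. One fit held the 15 whole cell libraries with a mean per day, with an F-test over the 5 days, and the other the 12 fraction libraries with a mean per fraction and day, which also gave the change of the ratio. Gene lists were tested with camera, from limma, at a preset correlation of 0.01 and again with an estimated correlation, and adjusted over the lists of a comparison. The lncRNAs as a set were tested the same way, adjusted over the 9 comparisons. The 25 lists were miR-290 and miR-302 targets, let-7 targets, microRNA machinery, naive and primed pluripotency, DNA methylation, germline genes, endoderm, mesoderm, neuroectoderm, trophoblast, fibroblast and 2-cell-stage markers, p53 targets, G1 to S regulators, interferon genes, stress response, glycolysis, imprinted genes, nuclear lncRNAs, snoRNA host genes, mitochondrial mRNAs, ribosomal proteins, secreted and membrane proteins, and SR splicing factors with Clk kinases. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

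The rule named the 8 genes with the largest rise and the 8 with the largest fall for whole cell day 12 and for nucleus against cytoplasm at day 0, and 3 and 3 in the other comparisons. They had to pass the test, reach 2 FPKM in 1 group and have all 3 replicates on 1 side of the other group. Predicted Gm, Rik and LOC models, pseudogenes and symbols that are not unique were left out. Up to 4 members of each called list were eligible, Dicer1, Malat1 and Neat1 were always given, and Cdkn1a, Rbl2, Lats2, Casp2, Dnmt3a, Dnmt3b, Pou5f1, Nanog, Sox2 and Mdm2 were followed throughout.

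Gene classes, coordinates and 3′ UTRs came from GENCODE M21 on GRCm38, matched by gene identifier, and no coordinate of mm9 was used. UTRs were found for 20411 of 21129 protein-coding genes. Seed sites were compared within 10 strata of UTR length and 5 of expression with 10000 stratified 2-sided permutations and 20 shuffled sites as background, using Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

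Alternatives were pseudocounts of 0.1 and 1, no filter, a mean FPKM of at least 1, median-of-ratios scaling, quantile normalization, the replicate number as a block, only the groups compared, and each library left out in turn. For site genes they were 7-mers, no strata and a pseudocount of 1. Those added after the data were seen left out the libraries labelled day 12 or the 2 nuclear libraries farthest from their group, or kept protein-coding and lncRNA genes alone. The comparisons of day 10 with day 4 and of the libraries labelled day 12 with day 10, and the tests between whole cell and fraction effects, were added then too. The limma step was tested on simulated data for 2 comparisons. For whole cell day 10 (15137 genes) it recovered 75.5% of genes changed by 1 on the log2 scale and 92.4% of those changed by 2, with 10 false calls among 169, and for the cytoplasm (15950 genes) 54.1% and 87.8%, with 8 among 147. A shift of 0.3 put into the site genes among 9408 genes came back as 0.3, which a difference of means gives by construction, so it checked the code alone.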

Results

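The series followed mouse embryonic stem cells through loss of Dicer, the RNase III enzyme that makes mature microRNAs from their precursors. The cells were an XY line with a conditional Dicer allele, grown on gelatin in serum with leukemia inhibitory factor. Culture with 4-hydroxytamoxifen at 800 nM deleted the RNase III domain, ethanol served as the control, and Dicer-deficient colonies were then expanded. By the labels no library after day 0 is an ethanol control, so loss of Dicer was not separated from drug, time or expansion. Whole cells were sequenced on 5 days, from day 0 to day 12 after the loss, and fractions on the first and last. Each of the 9 groups held 3 biological replicates. Between 12218 and 14023 genes per library reached 1 FPKM. Read totals were not among the values used here, but the steps between low FPKM values put the depth of the libraries at 0.721 to 3.62 times that of whole cell day 4 replicate 1, with a mean of 3.29 for whole cell day 0. Levels are mean FPKM ± SD (n = 3), and changes are on the log2(FPKM + 0.5) scale with the SE and the adjusted p of limma. For a gene list, the first pair of counts is of measured members past the threshold among all genes, and the second, within the list, is adjusted over the list alone. The camera adjusted p is given at the preset and then at an estimated correlation (estimated-correlation p, also adjusted), and ranges are of the adjusted p over the alternatives at the preset one.

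Dicer1, the targeted gene (chromosome 12, 104687742 to 104751952 on the minus strand, GRCm38), checks the labels. In whole cells it stood at 16.3 ± 1.47 FPKM at day 0, 1.41 ± 0.46 at day 4, 1.71 ± 0.17 at day 8 and 1.83 ± 0.12 at day 10. These later levels were 8.6%, 10.5% and 11.2% of day 0, and the log2 change at day 10 was -2.85 ± 0.16 (SE, adjusted p = 3.43e-08). The cytoplasm fell from 22.5 ± 1.18 to 3.06 ± 0.37 FPKM, 13.6% of day 0, and the nucleus from 13.3 ± 4.75 to 4.20 ± 1.11 FPKM, 31.6% of day 0. In the whole cell libraries labelled day 12, Dicer1 was at 14.6 ± 1.77 FPKM, 89.7% of day 0, with a log2 change of -0.16 ± 0.16 (SE, adjusted p = 0.58). The 3 libraries labelled day 12 held 16.7, 13.8 and 13.4 FPKM. An exact 2-sided permutation test gave p = 0.3 for these libraries and p = 0.1, the smallest that 3 against 3 allows, for each of the other groups. Dicer1 thus goes against the label of the whole cell day 12 libraries, and any direction drawn from them carries that reservation. FPKM is given per gene, so the deleted exons were not read separately.

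**Figure D1:**
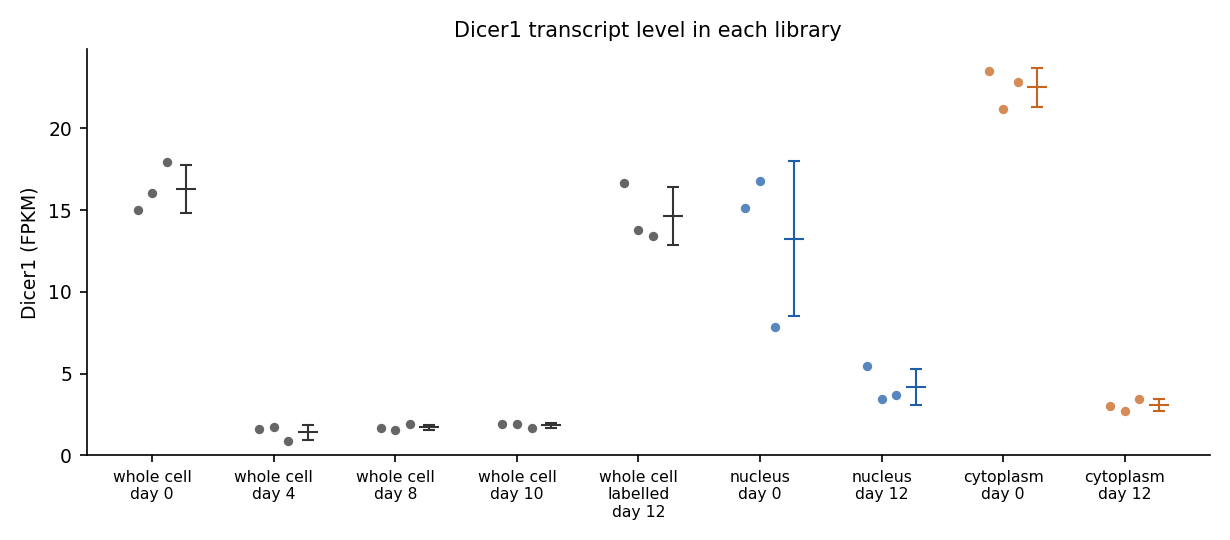
Dicer1 level in FPKM (vertical axis) in each of the 27 libraries by group (horizontal axis); points are libraries, the horizontal mark is the mean and the bar the SD (n = 3), with whole cell in dark grey, nucleus in blue and cytoplasm in orange. Whole cell days 4, 8 and 10 sit between 0.88 and 1.90 FPKM, while the whole cell libraries labelled day 12 sit between 13.4 and 16.7, beside those of day 0.

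At day 4, with Dicer1 already low, extraembryonic and definitive endoderm markers rose. Of these markers, 6 of 11 rose and 0 fell, or 9 and 0 within the list (camera adjusted p = 3.17e-08, estimated-correlation p of 0.00567). They included the basement membrane collagens Col4a2 and Col4a1 (log2 changes 1.07 and 0.96) and the transcription factors Gata4 and Sox17 (1.03 and 0.73). Among p53 target genes, 6 of 20 rose and 0 fell, or 7 and 0 within the list (camera adjusted p = 0.00121, estimated-correlation p of 0.106), led by the kinase gene Plk2 (0.67) and the cell cycle inhibitor gene Cdkn1a, which went from 26.0 ± 2.59 to 42.6 ± 13.3 FPKM, 0.66 ± 0.15 (SE, adjusted p = 0.0169). The Cdkn1a call ended without whole cell day 0 replicate 2 (adjusted p = 0.0842) or replicate 3 (0.0604) and with median-of-ratios scaling (0.0511). Of the glycolysis genes, 0 of 14 rose and 3 fell, or 0 and 5 within the list (camera adjusted p = 0.00121, estimated-correlation p of 0.198), with the phosphoglycerate kinase gene Pgk1 at -1.15.

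Of the published targets of the miR-290 and miR-302 families, the most abundant microRNAs of mouse embryonic stem cells, 3 of 18 rose and 0 fell, or 6 and 1 within the list (camera adjusted p = 0.0215, estimated-correlation p of 0.197) at day 4. That call ended without whole cell day 4 replicate 1 (adjusted p = 0.0596), range 0.00175 to 0.0596. Imprinted genes passed with 1 member past the threshold, Sgce at 0.45 (camera adjusted p = 0.0141, estimated-correlation p of 0.106). This call ended without whole cell day 4 replicate 2 (adjusted p = 0.126), range 0.00175 to 0.126. Of the ribosomal protein genes, 1 of 71 rose and 11 fell, or 1 and 13 within the list (camera adjusted p = 0.0233, estimated-correlation p of 0.812). It ended with median-of-ratios scaling (adjusted p = 0.0723), with quantile normalization (0.41), without whole cell day 0 replicate 1 (0.178), without whole cell day 4 replicate 1 (0.369) or replicate 2 (0.445, turning higher), range 1.90e-19 to 0.445. The largest falls by the fixed rule were Gapdh, a glycolytic enzyme gene (from 798 ± 80.9 to 72.1 ± 10.7 FPKM), Dynlt1b, a dynein light chain gene (from 91.8 ± 16.4 to 8.47 ± 2.11 FPKM), and Dicer1. Gapdh and Dynlt1b have near-identical copies in the genome, and their values are uncertain where reads can be divided among copies. The largest rises were Cmah (3.15 ± 0.40 SE, adjusted p = 0.000179), Olfr613 (from 0.906 ± 0.423 to 8.80 ± 2.05 FPKM) and Rny3, which was listed at 0 in every day 0 library. In all, 1071 of the 15991 genes tested passed, 780 higher and 291 lower. The share of higher genes was 72.8%, against 56.5% with quantile normalization, and without whole cell day 4 replicate 3 the count was 1721. It was 438 with only the 2 groups compared and 512 with protein-coding and lncRNA genes alone.

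At day 8 the miR-290 and miR-302 targets rose together. Of these genes, 14 of 18 rose and 1 fell, or 15 and 1 within the list (camera adjusted p = 7.99e-07, estimated-correlation p of 0.0155). Lats2, a kinase gene of the Hippo pathway and a cell cycle inhibitor, went from 0.655 ± 0.0944 to 5.68 ± 0.0885 FPKM, a log2 change of 2.42 ± 0.12 (SE, adjusted p = 3.21e-08), Cdkn1a reached 89.4 ± 2.26 FPKM (1.77), and the TGF-beta receptor gene Tgfbr2 rose by 1.81. Of the regulators of the G1 to S transition, 12 of 21 rose and 0 fell, or 13 and 0 within the list (camera adjusted p = 9.59e-05, estimated-correlation p of 0.0155), among them the cyclin gene Ccnd2 (2.24) and the inhibitor gene Cdkn2b (from 1.81 ± 0.127 to 5.18 ± 0.207 FPKM). For p53 targets, 13 of 20 rose and 0 fell, or 15 and 0 within the list (camera adjusted p = 3.04e-06, estimated-correlation p of 0.0222), with Btg2 at 1.57 and Perp at 1.46. Of the fibroblast and smooth muscle markers, 8 of 9 rose and 1 fell, or 8 and 1 within the list (camera adjusted p = 0.000101, estimated-correlation p of 0.0475). Acta2, Vim and Tagln, genes of the contractile and intermediate filament cytoskeleton, rose by 2.56, 2.04 and 1.80, Dcn, a proteoglycan gene, rose by 2.10, and Thy1, a surface glycoprotein gene, fell (-1.29).

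Other lists passed at day 8 with the preset correlation alone. In the neuroectoderm list 4 of 7 rose and 0 fell, or 5 and 0 within the list (camera adjusted p = 0.0214, estimated-correlation p of 0.0777), with Sox1 at 2.17. In the trophoblast list 4 of 10 rose and 0 fell, or 5 and 0 within the list (camera adjusted p = 0.0208, estimated-correlation p of 0.235), with the keratin genes Krt8 and Krt18 at 1.46 and 1.46. The trophoblast call ended with a mean FPKM of at least 1 (adjusted p = 0.0593), range 0.00436 to 0.0593. Of imprinted genes, 10 of 17 rose and 0 fell, or 10 and 2 within the list (camera adjusted p = 0.0313, estimated-correlation p of 0.0992). Of glycolysis genes, 0 of 14 rose and 8 fell, or 0 and 9 within the list (camera adjusted p = 1.44e-06, estimated-correlation p of 0.0567). Of the ribosomal protein genes, many of which have processed copies, 1 of 71 rose and 26 fell, or 1 and 29 within the list (camera adjusted p = 1.84e-10, estimated-correlation p of 0.463). The next 3 calls ended with quantile normalization. Endoderm markers gave an adjusted p of 0.0836 without whole cell day 8 replicate 3 (range 0.00787 to 0.0836, estimated-correlation p of 0.145). Stress response genes gave an adjusted p of 0.0543 without whole cell day 0 replicate 2 (range 0.0234 to 0.21, estimated-correlation p of 0.245). DNA methylation genes ranged over 0.00787 to 0.1 (estimated-correlation p of 0.463). The largest single rises were Olfr613 (3.13), Csf1, a macrophage growth factor gene (from 1.31 ± 0.357 to 13.2 ± 0.640 FPKM, 2.93 ± 0.23 SE, adjusted p = 1.29e-06), and Rny3, listed at 0 at day 0, and the largest falls were Dynlt1b, Gapdh and Dicer1. At this day 4769 genes passed, 3230 higher and 1539 lower, and the higher share of 67.7% became 56.9% with median-of-ratios scaling and 45.9% with quantile normalization.

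At day 10 the microRNA targets and the G1 to S regulators were higher and glycolysis genes lower than at day 0. Of the miR-290 and miR-302 targets 13 of 18 rose and 0 fell, or 13 and 1 within the list (camera adjusted p = 4.96e-06, estimated-correlation p of 0.0231). Lats2 (chromosome 14, 57689662 to 57758388, GRCm38) stood at 8.50 ± 0.210 FPKM against 0.655 ± 0.0944 at day 0, 2.97 ± 0.12 (SE, adjusted p = 2.14e-09). Cdkn1a (chromosome 17, 29090976 to 29100727) went from 26.0 ± 2.59 to 133 ± 4.21 FPKM, 2.34 ± 0.15 (SE, adjusted p = 1.21e-07). Casp2, a caspase gene, went from 2.67 ± 0.292 to 7.59 ± 0.243 FPKM, Rbl2, a member of the retinoblastoma gene family, from 0.837 ± 0.199 to 2.73 ± 0.236 FPKM, and Tgfbr2 and Irf2 rose by 2.57 and 2.08. In the G1 to S list 13 of 21 rose and 0 fell, or 14 and 0 within the list (camera adjusted p = 0.000319, estimated-correlation p of 0.0231), with Ccnd2 at 2.79, Cdkn2b at 2.37 and Cdkn2a at 2.09. In the p53 target list 14 of 20 rose and 0 fell, or 15 and 0 within the list (camera adjusted p = 4.72e-06, estimated-correlation p of 0.0231), with Plk2 at 2.04, Perp at 1.82 and Mdm2, the gene of the p53 ubiquitin ligase, at 1.07 ± 0.14 (SE, adjusted p = 4.18e-05). Of the glycolysis genes 0 of 14 rose and 10 fell, or 0 and 11 within the list (camera adjusted p = 7.86e-08, estimated-correlation p of 0.0397), and Pgk1, Pfkl, Pgam1 and Pfkp had log2 changes of -2.05, -1.29, -1.21 and -1.16.

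Of the core pluripotency factors at day 10 only Sox2 passed, and primed markers fell. Pou5f1 (log2 change 0.21 ± 0.09 SE, adjusted p = 0.0699) and Nanog (-0.11 ± 0.14 SE, adjusted p = 0.567) did not pass, and Sox2 fell, -0.38 ± 0.09 (SE, adjusted p = 0.00401). The naive list had 8 higher and 5 lower of 24, or 8 and 5 within the list, and did not pass (camera adjusted p = 0.822). In the primed list 1 of 12 rose and 7 fell, or 1 and 8 within the list (camera adjusted p = 0.000656, estimated-correlation p of 0.16), led by Otx2 (-2.02), Fgf5 (-1.49) and Lef1 (-1.23). The de novo DNA methyltransferase gene Dnmt3b, counted in the primed and the methylation lists, fell from 134 ± 20.2 to 45.2 ± 0.868 FPKM, -1.54 ± 0.15 (SE, adjusted p = 3.32e-06). In the methylation list 0 of 9 rose and 5 fell, or 0 and 5 within the list (camera adjusted p = 0.0107, estimated-correlation p of 0.373). Dnmt3a fell as well, -0.54 ± 0.13 (SE, adjusted p = 0.00442). The primed list, the methylation list, Dnmt3b and Dnmt3a did not pass at day 12 against day 0 in the nucleus or the cytoplasm, where Dicer1 was low. Germline genes that methylation silences did not pass as a list (4 higher and 1 lower of 13, or 4 and 0 within the list; camera adjusted p = 0.0788).

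Markers of other cell types were counted at day 10 as well. In the trophoblast list 6 of 10 rose and 1 fell, or 7 and 1 within the list (camera adjusted p = 0.0258, estimated-correlation p of 0.252), with Krt8 at 1.86, Krt18 at 1.71, Gata3 at 1.56 and Cdx2 at 1.13. That call ended with a mean FPKM of at least 1 (adjusted p = 0.0743), range 0.00213 to 0.0743. In the fibroblast list 7 of 9 rose and 1 fell, or 7 and 1 within the list (camera adjusted p = 0.0121, estimated-correlation p of 0.184), with Acta2 at 3.18 and Vim at 2.66. The endoderm list (5 higher and 0 lower of 11, or 6 and 0 within the list), the mesoderm list (3 higher and 0 lower of 9, or 3 and 0 within the list) and the neuroectoderm list (3 higher and 1 lower of 7, or 3 and 1 within the list) did not pass, with camera adjusted p of 0.0894, 0.32 and 0.172. A single 2-cell-stage marker was measured in whole cells and it did not pass, and no mitochondrially encoded mRNA of the list was measured.

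In the stress response list 2 of 13 rose and 7 fell, or 2 and 7 within the list (camera adjusted p = 0.0304, estimated-correlation p of 0.252), with Chac1 and Phgdh at -1.50 and -0.77 and Cth at 0.85. This call ended with quantile normalization (adjusted p = 0.159), range 0.00661 to 0.159. Of the ribosomal protein genes 1 of 71 rose and 46 fell, or 1 and 53 within the list (camera adjusted p = 1.27e-14, estimated-correlation p of 0.344), and many of them have processed copies elsewhere in the genome. The lists that did not pass are given as members higher, members lower and camera adjusted p: let-7 targets (5 and 4 of 16, or 6 and 4 within the list, 0.893), microRNA machinery (4 and 1 of 12, or 4 and 1 within the list, 0.859), interferon genes (3 and 2 of 9, or 3 and 2 within the list, 0.893), imprinted genes (7 and 2 of 17, or 8 and 2 within the list, 0.32), nuclear lncRNAs (1 and 0 of 6, or 1 and 0 within the list, 0.859), snoRNA host genes (3 and 4 of 10, or 3 and 4 within the list, 0.338), secreted and membrane proteins (11 and 1 of 26, or 11 and 2 within the list, 0.0729) and SR splicing factors (1 and 2 of 15, or 1 and 2 within the list, 0.223). Median, mean and test differed in sign for the let-7 target, naive pluripotency, interferon, nuclear lncRNA and snoRNA host lists. The largest single rises were Olfr613, Msln, a surface glycoprotein gene of mesothelium (chromosome 17, 25748613 to 25754378; from 0.773 ± 0.148 to 21.9 ± 1.97 FPKM, 4.14 ± 0.17 SE, adjusted p = 2.05e-09), and Thbs1, the thrombospondin 1 gene (from 4.85 ± 1.60 to 69.0 ± 2.20 FPKM). The largest falls were Gapdh (-3.57), Dynlt1b (-3.55) and Pim2, a serine/threonine kinase gene (chromosome X, 7878262 to 7883432; from 99.8 ± 7.98 to 8.15 ± 1.40 FPKM, -3.54 ± 0.11 SE, adjusted p = 3.27e-10). Of 15991 genes 6987 passed, 4427 higher and 2560 lower. The higher share of 63.4% became 44.4% with quantile normalization, which moves the median of all genes from 0.09 to -0.08.

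In the whole cell libraries labelled day 12, in which Dicer1 was not low, the microRNA target genes Lats2 and Casp2 did not pass against day 0. Lats2 was at 0.901 ± 0.0482 FPKM (0.28 ± 0.12 SE, adjusted p = 0.153) and Casp2 at 2.39 ± 0.0895 (-0.13 ± 0.10 SE, adjusted p = 0.467). Cdkn1a was at 43.4 ± 1.58 FPKM, 0.73 ± 0.15 (SE, adjusted p = 0.00673). The miR-290 and miR-302 target list did not pass (5 higher and 1 lower of 18, or 5 and 1 within the list; camera adjusted p = 0.235), nor did p53 targets (4 higher and 0 lower of 20, or 9 and 0 within the list; 0.204) or G1 to S regulators (5 higher and 1 lower of 21, or 5 and 1 within the list; 0.809). In the primed list 1 of 12 rose and 5 fell, or 1 and 7 within the list (camera adjusted p = 0.000101, estimated-correlation p of 0.302), with Otx2 at -1.23. Of the methylation genes 0 of 9 rose and 4 fell, or 0 and 4 within the list (camera adjusted p = 0.000526, estimated-correlation p of 0.354), with Dnmt3b at -0.91 ± 0.15 (SE, adjusted p = 0.00132) and Dnmt3a at -0.85. Of the fibroblast markers 5 of 9 rose and 0 fell, or 5 and 0 within the list (camera adjusted p = 0.0221, estimated-correlation p of 0.354). Of the SR factors 1 of 15 rose and 5 fell, or 1 and 6 within the list (camera adjusted p = 0.00241, estimated-correlation p of 0.354).

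The 8 largest rises of the libraries labelled day 12 against day 0 were Cmah (2.93), Platr2 (2.27), Hsd3b2 (2.19), the snoRNA host gene Gas5 (from 2.02 ± 0.656 to 10.5 ± 0.988 FPKM), H2-Q6 (2.03), Fam221b (2.01), Olfr613 (1.90) and Rprl3, listed at 0 at day 0. The 8 largest falls were Gapdh (-3.32), Dynlt1b (-3.16), Rex2 (-2.89), the histone genes Hist1h4c, Hist1h3c and Hist1h4h (-2.86, -1.99 and -1.96) and the zinc finger genes Zfp986 and Zfp987 (-2.67 and -2.57). Rex2, the histone genes and the Zfp pair belong to families of near-identical copies and are uncertain. In these libraries 3 calls ended with quantile normalization. Trophoblast markers gave an adjusted p of 0.107 without whole cell day 0 replicate 1 and 0.084 without whole cell day 12 replicate 1 (range 0.0121 to 0.132, estimated-correlation p of 0.354). Imprinted genes gave an adjusted p of 0.0529 without whole cell day 0 replicate 2, 0.0564 without whole cell day 12 replicate 1 and 0.0565 without replicate 3 (range 0.0232 to 0.133, estimated-correlation p of 0.302). Ribosomal protein genes gave an adjusted p of 0.081 without whole cell day 12 replicate 1 (range 0.000116 to 0.139, estimated-correlation p of 0.607). In these libraries 2170 genes passed, 1636 higher and 534 lower (75.4% higher, 56.9% with median-of-ratios scaling and 44.9% with quantile normalization), and the count was 1062 without whole cell day 0 replicate 2, 1380 without day 12 replicate 2 and 1377 without day 12 replicate 3. It was 3793 with only the 2 groups compared.

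Whole cell day 0 differed from every later whole cell group, those labelled day 12 included, in genes with near-identical copies. Of 1034 pseudogenes tested, 350, 476 and 502 were higher than day 0 at days 4, 8 and 10, and 460 in the libraries labelled day 12, with a median log2 change of 0.90 at day 10. Gapdh was at 798 ± 80.9 FPKM at whole cell day 0, and at 72.1 ± 10.7 at day 4. In the fractions of day 0 it was at 50.05 ± 2.32 FPKM in the cytoplasm and 33.96 ± 3.378 in the nucleus. Olfr613 was also among the largest rises of each later whole cell group. Cmah was among those of day 4 and of the libraries labelled day 12, where Dicer1 was not low. These rises cannot be told apart from a difference of whole cell day 0 itself. Among protein-coding and lncRNA genes alone, 512 passed at day 4. Comparisons without the day 0 libraries, chosen after this was seen, gave 5988 genes for day 10 against day 4 (3718 higher and 2270 lower, 2735 with only the 2 groups compared) and 7319 for the libraries labelled day 12 against day 10 (3294 higher and 4025 lower). With quantile normalization the majority turned in both, to 2991 higher and 3139 lower and to 3839 higher and 3745 lower. Across all 5 whole cell groups, 8663 genes passed the F-test of limma.

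Genes whose 3′ UTR carries a site for the miR-290, miR-302 and miR-17 families rose relative to genes without one. The site genes had at least 1 of the 8-mers AGCACTTA and GCACTTTA in an annotated 3′ UTR, and the others had no copy of the 6-mer GCACTT there. In whole cells 1009 site genes were compared with 8399 others within strata of UTR length and expression. At day 10 their log2 change was higher by 0.268 ± 0.003 (SD over n = 3 libraries, permutation p = 1e-04), and 75.0% of site genes against 50.8% of the others were higher than day 0. The difference was 0.072 ± 0.002 at day 4 and 0.211 ± 0.016 at day 8 (n = 3, permutation p = 1e-04 for each), and 0.197 ± 0.003 for day 10 against day 4, a comparison with no day 0 library. The whole cell libraries labelled day 12, in which Dicer1 goes against the label, gave 0.002 ± 0.008 against day 0 (n = 3, permutation p = 0.837) and -0.266 ± 0.008 against day 10 (permutation p = 1e-04). In the fractions, with 1043 site genes and 8781 others, day 12 against day 0 gave 0.218 ± 0.016 in the nucleus and 0.285 ± 0.005 in the cytoplasm (n = 3, permutation p = 1e-04 for each). The smallest p that 10000 permutations can give is 1e-04, the adjusted p over the 8 comparisons was 0.000114 for the 7 that passed, and 20 shuffled 8-mers of the same bases gave -0.105 to 0.103. The SD is the spread over the later libraries alone, and genes are not independent replicates.

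**Figure D2:**
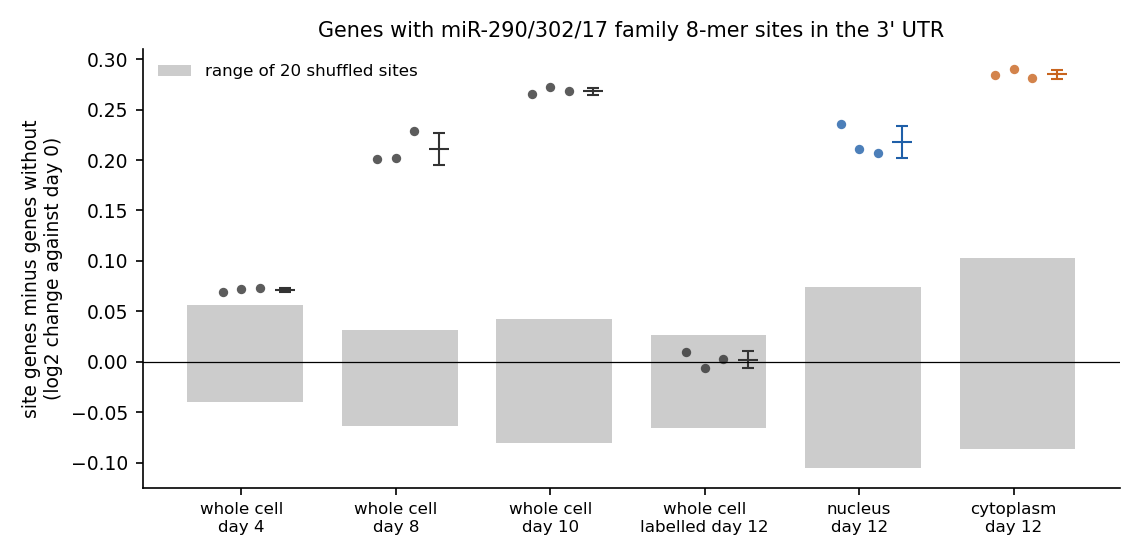
Difference in log2 change against day 0 between genes with an 8-mer site and genes without the 6-mer (vertical axis, log2) for 6 comparisons (horizontal axis); points are libraries, the mark and bar are the mean and SD (n = 3), and the grey band is the range of 20 shuffled sites. Whole cell day 10 is at 0.268, above its band of -0.08 to 0.042, and the whole cell libraries labelled day 12 are at 0.002, inside their band of -0.066 to 0.027.

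**Figure D3:**
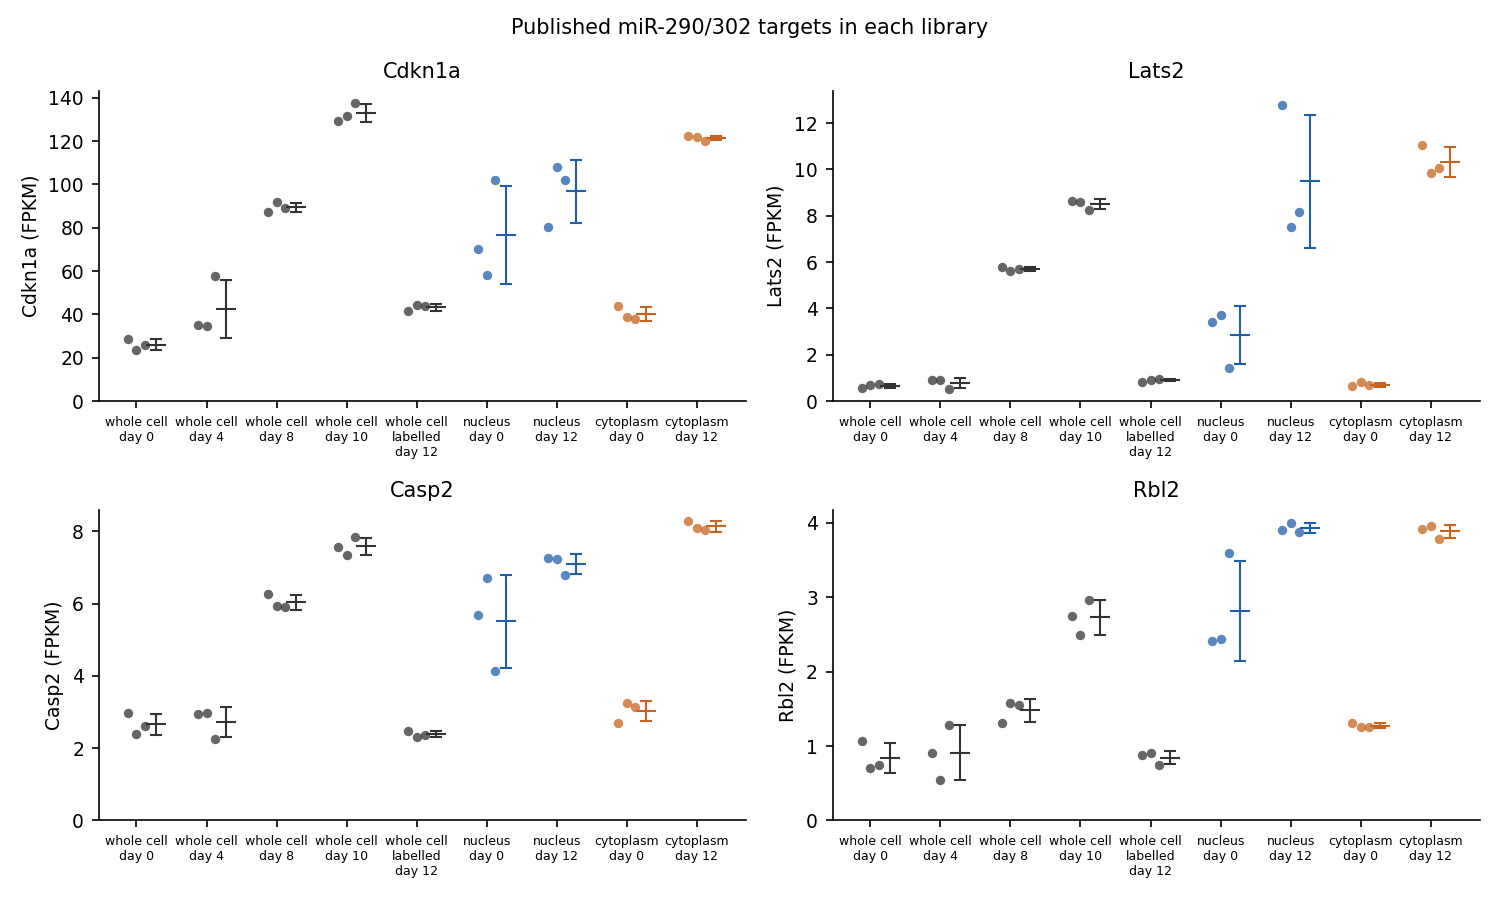
Level in FPKM (vertical axes, from 0) of 4 published miR-290 and miR-302 targets, Cdkn1a, Lats2, Casp2 and Rbl2, in each library by group (horizontal axes); points are libraries, and the mark and bar are the mean and SD (n = 3). Lats2 stood at 8.50 ± 0.210 FPKM in whole cells at day 10 and at 10.3 ± 0.638 FPKM in the cytoplasm at day 12, and at 0.901 ± 0.0482 FPKM in the whole cell libraries labelled day 12.

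The series asks how lncRNAs and mRNAs relate, and lncRNAs lay more in the nucleus than mRNAs did. At day 0 the median log2 nucleus to cytoplasm ratio was 0.413 ± 0.045 for 1573 lncRNA genes and 0.066 ± 0.012 for 13395 protein-coding genes (SD over n = 3 nuclear replicates, each against the cytoplasm mean). At day 12 the medians were 0.314 ± 0.023 and 0.012 ± 0.024. The lncRNA set was shifted toward the nucleus relative to the other genes on both days (camera adjusted p = 0.00199 at day 0 and 0.000695 at day 12, estimated-correlation p of 0.00101 and 9e-04). At day 0, 558 lncRNAs (35.5%) were higher in the nucleus and 132 (8.4%) lower, against 3229 (24.1%) and 2418 (18.1%) of the protein-coding genes. At day 12 the lncRNA counts were 399 and 86. The change of the ratio from day 0 to day 12 did not set the lncRNAs apart from the other genes (camera adjusted p = 0.871), with 1 lncRNA higher and 12 lower.

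**Figure D4:**
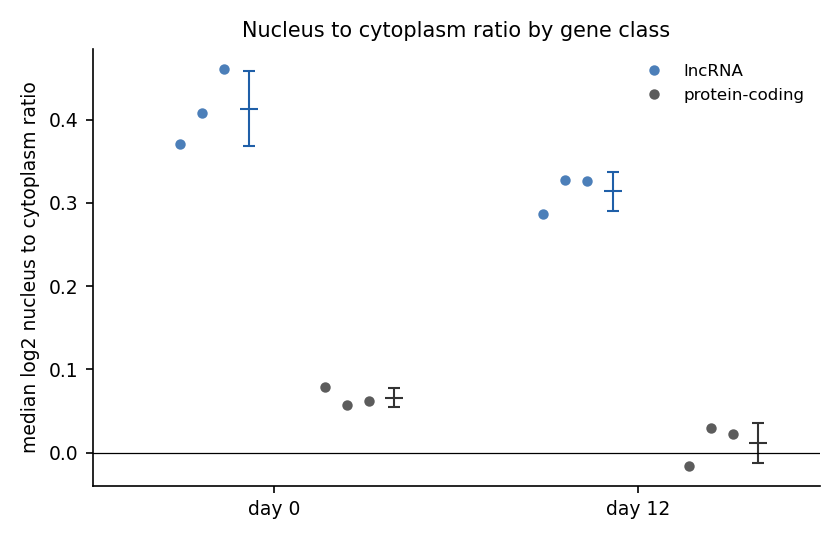
Median log2 nucleus to cytoplasm ratio (vertical axis) of lncRNA genes (blue) and protein-coding genes (grey) at days 0 and 12 (horizontal axis); points are replicates, and the mark and bar are the mean and SD (n = 3). The lncRNA medians sit between 0.287 and 0.461 and the protein-coding medians between -0.016 and 0.079.

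In whole cells, 201 of the 1258 lncRNAs tested rose and 154 fell at day 10 (16% and 12.2%), against 3638 and 2288 of 12823 protein-coding genes (28.4% and 17.8%). As a set the lncRNAs lay lower than the other genes at day 8 (102 rose and 109 fell, camera adjusted p = 0.0248, estimated-correlation p of 0.42). They also lay lower in the libraries labelled day 12 (50 and 29, camera adjusted p = 0.0316, estimated-correlation p of 0.42). At day 4 (36 and 19) and at day 10 the set did not pass, with camera adjusted p of 0.0874 and 0.146. The median lncRNA log2 change at day 10 was 0.008, on the other side of 0 from the test. The other genes in these tests held 1034 pseudogenes, which stood above whole cell day 0. Their median log2 change was 0.832 at day 8 and 0.949 in the libraries labelled day 12.

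In cells with Dicer at day 0, known nuclear lncRNAs and transcripts of secreted proteins were higher in the nuclear fraction. Transcripts of glycolytic enzymes and naive pluripotency factors were higher in the cytoplasmic one. Here and below, nucleus and cytoplasm mean these fractions, and cytoplasmic material left in all nuclear libraries was not excluded. Malat1 (chromosome 19, 5795690 to 5802672, GRCm38), a lncRNA of nuclear speckles, stood at 286 ± 113 FPKM in the nucleus and 16.4 ± 1.23 in the cytoplasm, 4.01 ± 0.38 (SE, adjusted p = 2.93e-05), and Neat1, the lncRNA of paraspeckles, was higher by 2.02 ± 0.20 (SE, adjusted p = 3.38e-05). Of the nuclear lncRNA list, 8 of 9 were higher and 0 lower in the nucleus, or 8 and 0 within the list (camera adjusted p = 3.02e-05, estimated-correlation p of 0.0838), with Meg3 and Mirg at 3.47 and 2.64. Of the snoRNA host genes, 8 of 10 were higher and 0 lower in the nucleus, or 9 and 0 within the list (camera adjusted p = 9.11e-06, estimated-correlation p of 0.129), with Snhg11 at 3.50 and Gas5 at 3.04. Of the secreted and membrane protein genes, 16 of 26 were higher and 0 lower in the nucleus, or 17 and 0 within the list (camera adjusted p = 0.000182, estimated-correlation p of 0.315), with the fibronectin gene Fn1 at 1.87 and the perlecan gene Hspg2 at 1.73. Of the SR splicing factor and Clk kinase genes, 12 of 15 were higher and 2 lower in the nucleus, or 12 and 3 within the list (camera adjusted p = 0.00594, estimated-correlation p of 0.427), with Clk1 at 1.85 and Clk4 at 1.81. Of the glycolysis genes, 0 of 14 were higher and 9 lower in the nucleus, or 0 and 10 within the list (camera adjusted p = 3.72e-05, estimated-correlation p of 0.0838), with Pkm at -1.46 and Pgam1 at -1.42. Of the naive pluripotency genes, 2 of 24 were higher and 12 lower in the nucleus, or 2 and 13 within the list (camera adjusted p = 0.000182, estimated-correlation p of 0.315), with Esrrb at -1.41 and Nr5a2 at -1.23.

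Collagen genes led the markers of other cell types in the nuclear fraction of day 0. In the fibroblast list 8 of 10 were higher and 0 lower in the nucleus, or 8 and 0 within the list (camera adjusted p = 0.00463, estimated-correlation p of 0.427), with Col1a1 at 4.45 and Col1a2 at 3.95. In the endoderm list 6 of 8 were higher and 0 lower in the nucleus, or 7 and 0 within the list (camera adjusted p = 0.000604, estimated-correlation p of 0.186), with Col4a2 at 3.53 and Col4a1 at 3.06. The largest nuclear excesses were the microRNA genes Mir294, Mir290a, Mir293, Mir291a and Mir295 (5.75, 5.41, 5.35, 5.27 and 4.93), neighbours on chromosome 7. Then came the spectrin gene Sptbn1 (195 ± 119 against 3.76 ± 0.235 FPKM) and the snoRNAs Snord83b (5.10) and Snord87 (110.3 ± 15.9 against 3.05 ± 0.441 FPKM). MicroRNA and snoRNA genes can be shorter than the 100-base reads and are uncertain. The largest cytoplasmic excesses were the tubulin gene Tubb3 (-1.91 ± 0.33 SE, adjusted p = 0.00108), Eno1b (-1.72), Dnmt3b (-1.71), the purine synthesis gene Ppat (-1.57), Teddm2 (-1.56), Ccdc85c (-1.55), the nucleoporin gene Nup98 (-1.48) and the Hedgehog receptor gene Ptch1 (-1.46). The Ccdc85c call ended without cytoplasm day 0 replicate 1 (0.0553) or replicate 2 (0.0516), that of Nup98 without cytoplasm day 0 replicate 1 (0.0527), and that of Ptch1 without cytoplasm day 0 replicate 1 (0.0806), replicate 2 (0.0523) or replicate 3 (0.0635), adjusted p in each, and over the alternatives the 3 genes ranged over 0.00378 to 0.0553, 0.000136 to 0.0527 and 0.00129 to 0.0806.

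In all, 7152 of the 17124 genes tested in the fractions passed between nucleus and cytoplasm at day 0, 4340 higher in the nucleus and 2812 lower. The share higher was 60.7%, against 39.4% with quantile normalization, which moves the median of all genes from 0.12 to -0.10, so the balance of the 2 directions rests on the scaling. Nucleus day 0 replicate 3 and day 12 replicate 1 stood apart from their groups, with mean correlations of 0.916 and 0.934 to the other 2 libraries, and without both the count was 10885. The next 5 list calls at day 0 did not hold in every alternative. Let-7 targets gave an adjusted p of 0.172 without nucleus day 0 replicate 3 (range 0.0083 to 0.289, estimated-correlation p of 0.599). Primed markers gave an adjusted p of 0.0712 without nucleus day 0 replicate 3 (range 0.0068 to 0.126, estimated-correlation p of 0.427). DNA methylation genes gave an adjusted p of 0.0712 without nucleus day 0 replicate 3 (range 0.0021 to 0.152, estimated-correlation p of 0.427). Stress response genes gave an adjusted p of 0.0553 without nucleus day 0 replicate 2 (range 0.00763 to 0.19, estimated-correlation p of 0.427). Ribosomal protein genes gave an adjusted p of 0.192 without nucleus day 0 replicate 1 and 0.532 without replicate 2 (range 1.34e-10 to 0.944, estimated-correlation p of 0.767).

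At day 12, after Dicer loss, nuclear lncRNAs and snoRNA host genes were again higher in the nucleus and glycolysis genes higher in the cytoplasm. Malat1 stood at 186 ± 92.7 against 17.4 ± 1.58 FPKM, 3.22 ± 0.38 (SE, adjusted p = 0.000166), and Neat1 at 1.88 ± 0.20 (SE, adjusted p = 8.81e-05). Of the nuclear lncRNA list, 7 of 9 were higher and 0 lower in the nucleus, or 7 and 0 within the list (camera adjusted p = 2.79e-05, estimated-correlation p of 0.0886). Of the snoRNA host genes, 7 of 10 were higher and 0 lower in the nucleus, or 7 and 0 within the list (camera adjusted p = 4.69e-05, estimated-correlation p of 0.209). Of the secreted and membrane protein genes, 13 of 26 were higher and 0 lower in the nucleus, or 14 and 0 within the list (camera adjusted p = 0.00065, estimated-correlation p of 0.347), with Fn1 at 2.96. Of the endoderm markers, 6 of 8 were higher and 0 lower in the nucleus, or 6 and 1 within the list (camera adjusted p = 0.00261, estimated-correlation p of 0.213). Of the glycolysis genes, 1 of 14 were higher and 9 lower in the nucleus, or 1 and 10 within the list (camera adjusted p = 4.69e-05, estimated-correlation p of 0.0886). Of the stress response genes, 1 of 13 were higher and 9 lower in the nucleus, or 3 and 9 within the list (camera adjusted p = 0.00569, estimated-correlation p of 0.347). Of the 2-cell-stage markers, a family of near-identical copies, 5 of 7 were higher and 1 lower in the nucleus, or 6 and 1 within the list (camera adjusted p = 0.0172, estimated-correlation p of 0.213), with Zscan4d at 1.24. The largest nuclear excesses were Sptbn1 (5.13), Lima1 (4.98) and Iqgap1 (4.82), genes of the actin and spectrin cytoskeleton. The largest cytoplasmic excesses were the transcription factor genes Tcf15 (-1.82) and Foxi3 (-1.69) and the selenoprotein gene Selenow (-1.79).

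Between the fractions at day 12, 5837 genes passed, 3156 higher in the nucleus and 2681 lower, and the share higher of 54.1% became 39.6% with quantile normalization, where the median of all genes moves from 0.06 to -0.08. Without the pair of nuclear libraries that stood apart the count was 10197. Between the fractions at day 12 the next 7 list calls did not hold in every alternative. Primed markers ranged over 0.00139 to 0.0855 (estimated-correlation p of 0.347). Interferon genes ranged over 0.00382 to 0.14 (estimated-correlation p of 0.347). G1 to S regulators ranged over 0.00323 to 0.139 (estimated-correlation p of 0.347). Let-7 targets gave an adjusted p of 0.0796 without nucleus day 12 replicate 2 and 0.0695 without replicate 3 (range 0.00704 to 0.283, estimated-correlation p of 0.506). Naive pluripotency genes gave an adjusted p of 0.272 without nucleus day 12 replicate 1 (range 0.00713 to 0.459, estimated-correlation p of 0.423). The p53 targets gave an adjusted p of 0.114 without nucleus day 12 replicate 2, 0.0926 without replicate 3 and 0.0533 without cytoplasm day 12 replicate 2 (range 0.00256 to 0.459, estimated-correlation p of 0.366). Ribosomal protein genes gave an adjusted p of 0.921 without nucleus day 12 replicate 1, turning higher and 0.551 without nucleus day 0 replicate 3 and day 12 replicate 1 together, turning higher (range 0.000135 to 0.921, estimated-correlation p of 0.739).

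In the cytoplasm at day 12, against day 0, the miR-290 and miR-302 targets and G1 to S regulators were higher and glycolysis genes lower. Of the miR-290 and miR-302 targets, 13 of 19 rose and 3 fell, or 13 and 3 within the list (camera adjusted p = 3.66e-05, estimated-correlation p of 0.0523). Lats2 went from 0.721 ± 0.0860 to 10.3 ± 0.638 FPKM, 3.15 ± 0.28 (SE, adjusted p = 2.15e-05), Cdkn1a from 40.3 ± 3.31 to 121 ± 1.05 FPKM, 1.58 ± 0.19 (SE, adjusted p = 0.000134), and Rbl2 from 1.28 ± 0.0294 to 3.89 ± 0.0888 FPKM. Casp2, Tgfbr2 and Irf2 rose by 1.29, 3.03 and 2.16. Of the G1 to S regulators, 11 of 21 rose and 1 fell, or 11 and 2 within the list (camera adjusted p = 0.000869, estimated-correlation p of 0.178), with Ccnd2 at 3.46 and Cdkn2a at 2.50. Of the p53 targets, 10 of 20 rose and 1 fell, or 11 and 1 within the list (camera adjusted p = 0.00453, estimated-correlation p of 0.251), with Perp at 1.78 and Mdm2 at 0.62 ± 0.15 (SE, adjusted p = 0.00865). Of the glycolysis genes, 0 of 14 rose and 7 fell, or 1 and 7 within the list (camera adjusted p = 0.00522, estimated-correlation p of 0.178). Of the secreted and membrane protein genes, 11 of 26 rose and 1 fell, or 11 and 1 within the list (camera adjusted p = 0.00588, estimated-correlation p of 0.428). Of the 2-cell-stage markers, 5 of 7 rose and 0 fell, or 5 and 0 within the list (camera adjusted p = 0.00623, estimated-correlation p of 0.17). Of the ribosomal protein genes, 0 of 71 rose and 5 fell, or 0 and 0 within the list (camera adjusted p = 0.000555, estimated-correlation p of 0.707).

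The largest rises in the cytoplasm at day 12 were Pla2g7, a phospholipase gene (from 0.260 ± 0.0748 to 11.1 ± 0.579 FPKM), Msln (3.81) and Notum, a Wnt-inactivating carboxylesterase gene (3.71) that overlaps or lies antisense to neighbours and is uncertain. The largest falls were Ndufa4l2 (-3.86), the retinoic acid binding protein gene Crabp1 (-3.63) and Dppa3, a gene of naive stem cells and germ cells (-3.51). Pou5f1 and Nanog had log2 changes of 0.07 ± 0.26 (SE, adjusted p = 0.882) and -0.27 ± 0.27 (SE, adjusted p = 0.489). Sox2 fell, with a log2 change of -0.518 (adjusted p = 0.02), and kept the call in 10 of 14 alternatives (range 8.39e-05 to 0.0774). Neat1 rose by 0.638 (adjusted p = 0.0293) and kept the call in 7 of 14 (range 0.00288 to 0.101), and Malat1 did not pass. The fibroblast list did not pass (3 higher and 1 lower of 10, or 3 and 1 within the list, camera adjusted p = 0.605). In the cytoplasm 3 calls ended with a mean FPKM of at least 1 as the filter. Neuroectoderm markers ranged over 0.00933 to 0.133 (estimated-correlation p of 0.392). Trophoblast markers ranged over 0.00346 to 0.0671 (estimated-correlation p of 0.17). Endoderm markers ranged over 0.0255 to 0.12 (estimated-correlation p of 0.41). In all, 5574 genes passed, 2738 higher and 2836 lower, and 10114 passed without the 2 nuclear libraries that stood apart, which share the estimate of the spread, and 9841 with only the 2 groups compared.

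In the nucleus at day 12, against day 0, microRNA targets, interferon genes and 2-cell-stage markers were higher and snoRNA host genes lower. Of the miR-290 and miR-302 targets, 10 of 19 rose and 2 fell, or 12 and 2 within the list (camera adjusted p = 0.00124, estimated-correlation p of 0.108), with Lats2 going from 2.86 ± 1.24 to 9.50 ± 2.87 FPKM, 1.62 ± 0.28 (SE, adjusted p = 0.00144). Cdkn1a went from 76.8 ± 22.7 to 96.8 ± 14.5 FPKM, 0.36 ± 0.19 (SE, adjusted p = 0.155). Of the interferon genes, 7 of 15 rose and 2 fell, or 7 and 2 within the list (camera adjusted p = 0.00164, estimated-correlation p of 0.297), with Rsad2 at 2.91. Of the 2-cell-stage markers, 6 of 7 rose and 0 fell, or 6 and 0 within the list (camera adjusted p = 5.53e-05, estimated-correlation p of 0.0603), with Zscan4f at 1.92. Of the G1 to S regulators, 6 of 21 rose and 2 fell, or 7 and 2 within the list (camera adjusted p = 0.00583, estimated-correlation p of 0.297). Of the snoRNA host genes, 0 of 10 rose and 8 fell, or 0 and 8 within the list (camera adjusted p = 0.000222, estimated-correlation p of 0.219), with Epb41l4aos at -1.88. Of the glycolysis genes, 1 of 14 rose and 7 fell, or 1 and 8 within the list (camera adjusted p = 0.029, estimated-correlation p of 0.313), with Pfkp at -1.80. Malat1 (-0.71 ± 0.38 SE, adjusted p = 0.167) and Neat1 (0.51 ± 0.20 SE, adjusted p = 0.067) did not pass. The largest rises were Myadml2os, Notumos and Notum (4.25, 4.11 and 3.98), which overlap or lie antisense to neighbours on chromosome 11 and are uncertain. The largest falls were the collagen gene Col1a2 (-3.75), Crabp1 (-3.29) and Ndufa4l2 (-3.24).

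In the nucleus 6281 genes passed between day 12 and day 0, 2585 higher and 3696 lower. Without nucleus day 0 replicate 3 and day 12 replicate 1 the count was 9613, and with only the 2 groups compared it was 2112. With median-of-ratios scaling 2915 were higher and 3160 lower, and with quantile normalization 3004 and 3151. In the nucleus 8 list calls did not hold in every alternative. MicroRNA machinery genes gave an adjusted p of 0.124 without nucleus day 12 replicate 1 (range 0.0118 to 0.139, estimated-correlation p of 0.421). Neuroectoderm markers gave an adjusted p of 0.0731 without nucleus day 12 replicate 1 (range 0.00786 to 0.139, estimated-correlation p of 0.369). Trophoblast markers gave an adjusted p of 0.0585 without nucleus day 0 replicate 2 and 0.052 without nucleus day 12 replicate 2 (range 0.0141 to 0.13, estimated-correlation p of 0.219). Endoderm markers gave an adjusted p of 0.106 without nucleus day 0 replicate 3 and 0.0574 without nucleus day 12 replicate 1 (range 0.0212 to 0.139, estimated-correlation p of 0.369). Stress response genes gave an adjusted p of 0.0564 without nucleus day 12 replicate 2 and 0.0523 without replicate 3 (range 0.00855 to 0.0564, estimated-correlation p of 0.421). SR splicing factors gave an adjusted p of 0.0527 without nucleus day 0 replicate 2 (range 0.00417 to 0.0527, estimated-correlation p of 0.421). Secreted and membrane protein genes gave an adjusted p of 0.0565 without nucleus day 0 replicate 3, 0.0586 without nucleus day 12 replicate 2 and 0.0846 without replicate 3 (range 0.00697 to 0.0846, estimated-correlation p of 0.507). Ribosomal protein genes gave an adjusted p of 0.156 without nucleus day 0 replicate 3, 0.149 without nucleus day 12 replicate 1 and 0.102 without nucleus day 0 replicate 3 and day 12 replicate 1 together, turning higher (range 4.21e-06 to 0.156, estimated-correlation p of 0.823).

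At the preset correlation the nucleus to cytoplasm ratio was lower at day 12 than at day 0 for the lists of p53 targets, fibroblast markers and microRNA targets. Each had 3 members past the threshold, and no list passed for the ratio at an estimated correlation. Of the p53 targets, 0 of 20 rose and 3 fell, or 0 and 7 within the list (camera adjusted p = 0.000144, estimated-correlation p of 0.184), with Perp at -1.35 and Btg2 at -1.22. Of the fibroblast markers, 0 of 10 rose and 3 fell, or 0 and 5 within the list (camera adjusted p = 0.000759, estimated-correlation p of 0.393), with Col1a2 at -3.21 and Acta2 at -1.70. Of the miR-290 and miR-302 targets, 0 of 19 rose and 3 fell, or 0 and 11 within the list (camera adjusted p = 0.000909, estimated-correlation p of 0.105), with Tgfbr2 at -1.55 and Irf2 at -1.25, while Lats2 (-1.53 ± 0.39 SE, adjusted p = 0.0828) and Cdkn1a (-1.22 ± 0.26 SE, adjusted p = 0.0524) did not pass. The 2-cell-stage list had a higher ratio at the preset correlation alone (0 higher and 0 lower of 7, or 4 and 0 within the list, camera adjusted p = 9.36e-05, estimated-correlation p of 0.069). So had the naive pluripotency list, with most members not past the threshold (1 higher and 0 lower of 24, or 1 and 0 within the list, camera adjusted p = 0.00277, estimated-correlation p of 0.393), and Tfcp2l1 at 0.82. The snoRNA host genes (0 higher and 1 lower of 10, or 0 and 3 within the list, camera adjusted p = 0.000757, estimated-correlation p of 0.288) and SR splicing factors (0 higher and 2 lower of 15, or 0 and 4 within the list, camera adjusted p = 0.00277, estimated-correlation p of 0.393), with Srsf1 at -1.38, had a lower ratio at the preset correlation. The ratio compares relative FPKM values, so its change does not show movement of transcripts between nucleus and cytoplasm.

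For single genes the ratio rose most, by the fixed rule, for Myh14 (1.84), Tprn (1.83) and Sipa1l2 (1.36), and fell most for Snord91a (-3.24), Col1a2 and the cardiac lncRNA gene Mhrt (-2.35). Myh14, Tprn, Snord91a and Mhrt each lost the call without any 1 cytoplasmic library of day 12 or without cytoplasm day 0 replicate 1, and some of them without cytoplasm day 0 replicate 2 or 3, nucleus day 0 replicate 1 or 2 or nucleus day 12 replicate 2 or 3. Their adjusted p ranged over 0.00255 to 0.128, 0.000207 to 0.073, 0.0125 to 0.117 and 0.000118 to 0.0592 over the alternatives. In all 227 genes passed, 47 with a higher ratio and 180 with a lower one, a share higher of 20.7% that became 31.1% with median-of-ratios scaling and 40.9% with quantile normalization. The count was 1443 without nucleus day 0 replicate 3, 1699 without nucleus day 12 replicate 1, 6580 without both, and 24 to 220 without each of the other libraries in turn. With the replicate number as a block it was 53, 6 higher and 47 lower. The block also ended the calls of Myh14 (adjusted p = 0.094), Tprn (0.0556) and the G1 to S list (camera adjusted p = 0.0562). For the ratio 3 list calls did not hold in every alternative. G1 to S regulators gave an adjusted p of 0.171 without nucleus day 0 replicate 1, 0.185 without replicate 2, 0.0578 without cytoplasm day 0 replicate 2, 0.117 without nucleus day 12 replicate 1, 0.0533 without replicate 2, 0.0509 without cytoplasm day 12 replicate 1 and 0.0686 without replicate 2 (range 0.00417 to 0.185, estimated-correlation p of 0.409). DNA methylation genes gave an adjusted p of 0.221 without nucleus day 0 replicate 3 and 0.269 without nucleus day 12 replicate 1 (range 0.00819 to 0.962, estimated-correlation p of 0.506). Interferon genes gave an adjusted p of 0.103 without nucleus day 0 replicate 3 (range 0.001 to 0.103, estimated-correlation p of 0.393).

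Of the 4353 genes tested in both that were higher in whole cells at day 10, 2178 were also higher in the cytoplasm at day 12, a pair of comparisons with no library in common. Of all 15506 genes tested in both, 742 would be higher in both if the lists were independent, 1595 were lower in both (448 expected), and the log2 changes correlated across genes with r = 0.613. For the whole cell libraries labelled day 12, in which Dicer1 goes against the label, 234 genes were higher in both (272 expected) and 59 lower in both (91 expected), with r = -0.044. For day 8 r was 0.439 and for day 4 it was 0.129. Nucleus and cytoplasm shared 1632 genes higher at day 12 (413 expected) and 2008 lower (612 expected), with r = 0.712. Genes are not independent replicates, so no p is given for these correlations.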

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

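Of the tests in this part, the comparison of the day 12 effect between whole cells and fractions, those on outgrowth, on wrongly joined genes, on depth for Gapdh and on loss of Dicer as a source of the pseudogene shift, the pseudogene limit of 10 FPKM at day 0, the first test of cytoplasmic RNA and that on nucleus day 0 replicate 3 alone were chosen only after the result was seen, as were the comparisons of day 10 with day 4 and of the libraries labelled day 12 with day 10. The effect of day 12 against day 0 differed between whole cells and the fractions in a single limma fit of the 6 groups. For Dicer1 the difference on the log2 scale was 1.353 ± 0.31 (SE, adjusted p = 0.0035) against the nucleus and 2.541 ± 0.31 (SE, adjusted p = 2.47e-05) against the cytoplasm. In all 6663 of 17339 genes differed from the nucleus (4204 higher and 2459 lower in the whole cell effect) and 5962 from the cytoplasm (3474 and 2488). With median-of-ratios scaling they were 3215 higher and 3195 lower against the nucleus and 2872 and 2986 against the cytoplasm, and with quantile normalization 2942 and 3357, and 2708 and 2760. The majority direction therefore depends on the scaling. Of 100 splits of the libraries, 1, the real one, gave as many for each, a share under 0.05, with highest other counts of 4867 and 4111. That argues against a random grouping by day, but splits that mix days also move the day effects into the spread. They therefore do not show that the difference between the effects is beyond chance. The nucleus to cytoplasm ratio changed for 227 genes, the test of the difference between the fractions, and 8 of 100 splits, the real one included, gave as many. The 7 others all kept or exchanged the days of the whole cytoplasm and so still hold its day effect. The highest, with 8206 genes, kept all days of the cytoplasm and exchanged all of the nucleus, which adds up the day effects of the 2 fractions. The 79 splits that mixed the days in both gave at most 212 genes. These splits therefore leave open whether chance gave the 227.

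Dicer1 stood near its day 0 level in the whole cell libraries labelled day 12, and the test that bears on this used other genes. Site genes for the miR-290, miR-302 and miR-17 families differed from other genes by 0.002 in these libraries against 0.268 at day 10, so the libraries may come from cells that kept Dicer, whatever their label. Outgrowth of such cells over the whole day 12 culture is argued against by the cytoplasm labelled day 12, where the log2 change of Dicer1 was -2.696. Values joined to the wrong genes in these differently formatted files are argued against by a correlation of 0.984 across genes with whole cell day 4. A wrong label, a failed deletion in a separate culture and outgrowth in that culture alone remain open.

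Pseudogenes stood higher and Gapdh lower in every later whole cell group than in whole cell day 0, and the fractions help to place the shift. Pseudogenes in the cytoplasm at day 0 lay above whole cell day 0 by a median of 0.771, so whole cell day 0 itself may be the odd group, with reads shared between near-identical copies assigned differently. Loss of Dicer is argued against by the same pseudogenes in the cytoplasm, whose median change from day 0 to day 12 was 0.018. Gapdh in the fractions, compared only after the shift was seen, also argues against it. The cytoplasm held 50.05 ± 2.32 FPKM at day 0 and 52.47 ± 6.993 at day 12, and the nucleus 33.96 ± 3.378 and 34.86 ± 2.167. A difference in depth is argued against for Gapdh, which stood at 66.7 FPKM or more in every whole cell group and whose smallest log2 change from day 0 was -3.319 ± 0.117 (SE). For the pseudogenes it cannot be told apart from other causes. The 180 pseudogenes with a mean of at least 10 FPKM over all whole cell groups had a median change of 2.175 at day 10, but a rise itself brings genes over that limit. The 86 with at least 10 FPKM at day 0 had a median of 0.025, with quartiles of -0.541 and 1.007. Why whole cell day 0 differed, in the library or the processing, was not tested.

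Nucleus day 0 replicate 3, nucleus day 12 replicate 1 and whole cell day 4 replicate 3 correlated least with their groups, at mean r of 0.916, 0.934 and 0.936. Their deviations from the group mean followed transcript length with rho of -0.530, 0.426 and -0.546, the nearest to 0 being 0.426, so a length bias is a candidate explanation. It is not particular to them. Other libraries of these groups reached 0.53, because deviations sum to 0, and whole cell replicate 1 labelled day 12 and whole cell day 8 replicates 2 and 3, which did not stand apart, had rho of 0.391, -0.321 and 0.335. Cytoplasmic RNA in the 2 nuclear libraries, tested on nuclear lncRNAs, cannot be told apart from other causes, since the lower of the 2 medians was 0.257 and members went both ways. A second test on all protein-coding genes, chosen when the first did not decide, gave rho of 0.137 for nucleus day 12 replicate 1. That argues against more cytoplasmic RNA there than in the other 2 replicates, which gave -0.124 and -0.135. Each rho is relative to the other replicates, so cytoplasmic RNA in those 2 was not excluded. The pseudogene Gm13340 stood at 2069.4 FPKM in replicate 1 and at 24959.3 and 18965.4 FPKM in replicates 2 and 3. For nucleus day 0 replicate 3 rho was -0.002, and cytoplasmic RNA cannot be told apart from other causes in that library. No biological explanation was tested, since the design gives none within a group.

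Other splits of the libraries were counted for the remaining comparisons. Across the 5 whole cell groups, 1 of 100 splits, the real one, gave as many genes as the real 8663, the highest other being 877. This argues against a random grouping of these libraries. The other comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave as many in each. Real counts and highest others were 1071 and 2 at day 4, 4769 and 1 at day 8, 6987 and 1 at day 10, and 2170 and 2 for the libraries labelled day 12. They were 7152 and 1 between the fractions at day 0, 5837 and 2 at day 12, 6281 and 2029 in the nucleus, and 5574 and 1 in the cytoplasm. They were 5988 and 3 for day 10 against day 4 and 7319 and 3 for the libraries labelled day 12 against day 10.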

How the results depend on the processing

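In this part the settings without the libraries labelled day 12, with protein-coding and lncRNA genes alone and without the 2 nuclear libraries were chosen only after the result was seen. So were the tests between whole cell and fraction effects, of day 10 against day 4 and of the libraries labelled day 12 against day 10. Of 687 values of 48 results under the alternatives, 635 kept their direction and their side of the threshold or, for counts, stayed within 1.5 times. The other 52 changed, 4 of them by reversing.

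With only the groups compared in the fit, counts were 438 at day 4, 3793 in the libraries labelled day 12, 2112 in the nucleus and 9841 in the cytoplasm. They were 2735 for day 10 against day 4 and 9341 for whole cell minus cytoplasm, and the spread is then estimated from fewer libraries. Protein-coding and lncRNA genes alone, with fewer genes tested, gave 512 at day 4. Without nucleus day 0 replicate 3 and nucleus day 12 replicate 1, counts were 10885 and 10197 between the fractions at days 0 and 12. In the nucleus, the cytoplasm and the ratio they were 9613, 10114 and 6580, and the cause was not tested. With an estimated correlation, camera called 1 list at day 4, 4 at day 8 and 4 at day 10. It called 0 in the libraries labelled day 12, between the fractions at days 0 and 12, in the nucleus, the cytoplasm and the ratio, with 2, 4, 5, 4, 5 and 4 lists at an unadjusted p under 0.05. Quantile normalization gave 4 lists in the libraries labelled day 12 and 137 genes for the ratio. A mean FPKM of at least 1 gave 6 lists between the fractions at day 12 and 6 in the cytoplasm. The cause was not tested for these.

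Leaving out each library in turn changed 25 of 315 values. At day 4 the counts were 735 to 1721, with 1721 without whole cell day 4 replicate 3. In the libraries labelled day 12 they were 1062 to 1669, with 1062 without whole cell day 0 replicate 2, and 1380 and 1377 without replicates 2 and 3 of those libraries. The lists called there were 4 to 8, with 4 without replicate 1 of those libraries. For the ratio the counts were 24 to 1699, with 1443 without nucleus day 0 replicate 3 and 1699 without nucleus day 12 replicate 1. Without cytoplasm day 0 replicates 1, 2 and 3 they were 53, 55 and 34, and without cytoplasm day 12 replicates 1, 2 and 3 they were 24, 42 and 41. Without nucleus day 0 replicate 1 the count was 114, and without nucleus day 12 replicates 2 and 3 it was 83 and 94. Of the genes named for the ratio, 2 to 6 passed, with 2, 3 and 3 without cytoplasm day 0 replicates 1, 2 and 3 and 2 without each cytoplasm day 12 library. Counts at day 10 were 5722 to 6072, and those in the cytoplasm 4129 to 4216. The cause of these moves was not tested.

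The site gene difference in the libraries labelled day 12 was 0.002 and did not pass, so its sign carries little. Without strata it was -0.093 (permutation p = 1e-04, the smallest they can give), which leaves UTR length and expression uncorrected. Leaving out each library gave -0.004 to 0.013, with -0.001 without replicate 1 of those libraries and -0.003 and -0.004 without whole cell day 0 replicates 2 and 3.

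Replicate numbers did not pair the libraries. Same-numbered libraries deviated together with a mean r of -0.02 over 30 pairs in whole cells, 2 of them over 0.1, and -0.004 over 18 pairs in the fractions, 5 of them over 0.1. Of the 27 libraries 7 correlated best with their own number. The replicate block changed 1 of 40 values, to 53 genes for the ratio, and also ended 3 list calls and the calls of 4 named genes. Values of genes with low FPKM are limited by depth, and read totals were not used here.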

Other observations

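The genes and the test in this part were chosen after their values were seen. Some genes of the microRNA silencing complex rose after the loss of Dicer, although the microRNA machinery list did not pass in whole cells. Tnrc6a, of the GW182 family, went from 10.5 ± 0.854 to 34.0 ± 2.26 FPKM in whole cells at day 10, 1.65 ± 0.11 (SE, adjusted p = 1.35e-07). It rose by 1.80 in the cytoplasm and 0.81 in the nucleus at day 12. The Argonaute gene Ago1 rose by 1.28, 1.61 and 1.60 in the same comparisons. Both genes passed in each of 21 alternatives in whole cells and 18 in each fraction. Tnrc6b rose by 0.72, 1.03 and 1.34, and its whole cell call ended with quantile normalization (adjusted p = 0.0519, range 0.00353 to 0.0519). Tnrc6c, Ago2, Ago3 and Drosha did not pass in whole cells at day 10, with adjusted p of 0.0589, 0.872, 0.379 and 0.675, and Ago2 and Ago3 did not pass in the fractions. Tnrc6c and Drosha rose by 0.918 and 0.448 in the nucleus at day 12 (adjusted p = 0.000197 and 0.0102), each in 18 of 18 alternatives. In the cytoplasm Drosha did not pass (adjusted p = 0.282), and Tnrc6c rose by 0.394 (adjusted p = 0.0188). That call ended without cytoplasm day 0 replicate 2 (0.0693) or 3 (0.0673) and without cytoplasm day 12 replicate 1 (0.0574) or 3 (0.0624).

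Published let-7 targets went both ways. The RNA-binding protein gene Lin28a fell from 104 ± 3.20 to 31.6 ± 2.81 FPKM in whole cells at day 10, -1.70 ± 0.07 (SE, adjusted p = 3.10e-09), with log2 changes of -2.49 in the cytoplasm and -2.94 in the nucleus at day 12. The chromatin gene Hmga2 rose from 2.93 ± 0.332 to 8.09 ± 0.468 FPKM in whole cells at day 10, 1.33 ± 0.11 (SE, adjusted p = 6.64e-07). Its log2 changes of 1.41 in the cytoplasm and 0.045 in the nucleus did not pass (adjusted p = 0.0733 and 0.958). Among imprinted genes Plagl1 rose by 1.96 in whole cells at day 10, 2.73 in the cytoplasm and 2.55 in the nucleus, and Phlda2 had log2 changes of -1.23, -2.18 and -2.23. Lin28a, Plagl1 and Phlda2 kept direction and passed in all 21 and 18 alternatives. In the whole cell libraries labelled day 12, where Dicer1 was not low, they did not pass against day 0 (0.06, 0.06 and 0.19), while Hmga2 rose by 0.73.

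Genes with miR-290, miR-302 and miR-17 family sites rose in both fractions at day 12, by 0.218 in the nucleus and 0.285 in the cytoplasm, and the hypothesis that the rise arises after export from the nucleus was put to the change of the nucleus to cytoplasm ratio. The ratio of the 1043 site genes moved by -0.067 relative to the 8781 others (permutation p = 0.0002), and 20 shuffled sites gave -0.049 to 0.054. Leaving out each library in turn gave -0.076 to -0.06, with a highest permutation p of 0.0011. Leaving out both nucleus day 0 replicate 3 and nucleus day 12 replicate 1 gave -0.069 (permutation p = 0.002). The value is the difference of the 2 changes that prompted the hypothesis, so its direction was set before the test, and the hypothesis stays open. Cytoplasmic RNA shared by all nuclear libraries was not excluded as a source of the rise in the nucleus.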
